A study of Homo sapiens with 6 samples.

How the data were processed

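RNA of human primary corneal epithelial cells was measured on 6 Affymetrix Human Gene 1.0 ST arrays, 3 of wells that received control siRNA and 3 of wells that received H19 siRNA. Per the labels' protocols, 100000 cells per well were transfected with 30 nM siRNA for 72 hours before total RNA was isolated, amplified with a whole-transcript kit and labelled with biotin. The control pool and the H19 pool came from different suppliers, and the siRNA sequences are not given in the sources used here. Groups and replicate numbers were taken from the sample titles.

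The deposited values are a linear array intensity, 1 PLIER signal per transcript cluster, which the authors made with Affymetrix Expression Console 1.1.1 and PLIER 2.0, per the submitters' processing notes, with a gene-level default workflow, per the file headers. PLIER models the affinity of each probe and summarises the probes of a cluster. Background correction, between-array normalization and the annotation release are not given in the sources used here. The 2 deposited tables held identical values for all 33297 probe sets, so they were used as 1 source. Arrays have no read depth, and their number limits the precision. Signal over background was described by the share of pairs in which a positive control exceeded a negative control, which was 0.881 for control replicate 1 and between 0.895 and 0.902 for the other arrays.

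Signals were analysed as log2(signal + 16), so that fold changes are on that scale and understate the change of dim genes. Of the table's clusters 22075 carried exactly 1 gene symbol, 2 carried several and 7077 carried none, with 2904 negative controls, 1195 positive controls and 44 spike probe sets besides. Symbols are those of the table, which are old. Of the 22075 clusters 21618 matched a current gene by RefSeq accession, symbol or synonym, and 2965 of the current symbols differ. A gene with several clusters (1266 of 20218 genes) was represented by the cluster with the highest mean over all arrays, so RPL7, RPL34 and SDHD were read by clusters away from the genes' own loci. Coordinates are those of the table. Its build is not stated as such, but Ensembl descriptions in the table give GRCh37 positions, and 5015 of 5950 clusters with a single such range lay inside it. No genome was used.

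Genes whose mean lay at or below the median of the negative control probe sets (4.91) were left out, which kept 19322 of 20218 genes. The rule had been written for intron controls. The table marks these probe sets only as negative controls, so leaving out the lowest 25% of clusters, the rule's fallback, was added as an alternative after seeing the data.

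Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with an intensity trend, two-sided, Benjamini-Hochberg over the genes tested), with group as the sole term, and genes were called at an adjusted p under 0.05. The design, the alternatives, 36 lists of genes and cell type markers and the rule for named genes were fixed before the data were examined. Of 1032 list entries 1027 were found on the array, and lists with at least 5 tested genes were tested with camera at its preset correlation of 0.01, against all other genes tested. Called lists were 12, of which 3 shifted up and 9 down, and none was called with the correlation estimated from the data (4 lists had an unadjusted p under 0.05). Fry, which asks whether a list's own genes moved on balance in a direction and compares them with no other genes, called 17. Named genes are H19, the 12 largest rises and 12 largest falls among called genes whose groups do not overlap, and up to 4 members of each list with the smallest p. Genes without an assigned name, XIST and Y-linked genes were passed over, except that H19 is always named. Not every gene that meets this rule is given by name. Other list members given by name were chosen after their values were seen. Annotation terms of the deposited table with 15 to 300 tested genes, and 2 further lists, were tested in the same way and were chosen after the data were examined. Joins and figures used Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

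The fit was tested on simulated arrays with the means and spreads of the 19322 genes, 200 of them changed. It recovered 23.9% of changes of 0.5 on the log2 scale, 98.5% of changes of 1 and 100% of changes of 2, with 3.90% false calls, and made 0 calls with no change simulated. All 3 simulated list shifts were called and 0 other lists. The simulated genes varied independently of each other, with an equal spread in all arrays. The simulation therefore cannot show how the calls, of lists above all, fare with correlated genes or an outlying array. Alternatives covered offsets of 1 and 32, quantile normalization, centring, the filter on dim genes, the variance model, array weights, the replicate block, the mean of all clusters of a gene, the thresholds, the set test and leaving out each array.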

Results

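Gene expression was measured in human primary corneal epithelial cells, the cells that cover the front of the eye, 72 hours after transfection with 30 nM siRNA. In 3 wells the cells received a pool of siRNAs against H19, and in 3 wells a control siRNA pool. H19 is an imprinted long noncoding RNA. RNA from each well was hybridised to an Affymetrix Human Gene 1.0 ST array, so each group has n = 3. The median PLIER signal of the arrays ranged from 82.8 to 95.2, and the number of arrays limits the precision. The question, as the design states it, was how lowering H19 affects gene expression in these cells. The labels do not say that the wells came from separate donors or cultures, so p-values measure only the spread between these samples, which may be technical. Across genes, which are not independent replicates, the 3 H19 siRNA arrays correlated with their own group at a mean of 0.996, and control replicates 2 and 3 correlated with each other at 0.995. Control replicate 1 stood apart, with a mean correlation of 0.967 with the other controls.

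The target came first. H19 lies on chromosome 11 from 2016408 to 2019072, on the minus strand (GRCh37), and 26 probes measured it. Its level was 13.20 ± 0.07 (SD, n = 3) with control siRNA and 9.28 ± 0.17 (SD, n = 3) with H19 siRNA, on the log2(signal + 16) scale used for all levels here. This was a log2 change of -3.92 with a standard error of 0.10, or 15.1-fold lower, at an adjusted p of 3.74e-06 by limma. The control arrays read 13.12, 13.22 and 13.26, and the H19 siRNA arrays 9.17, 9.48 and 9.20, so every array followed its label.

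Near H19, the clusters named INS-IGF2 and IGF2 were higher. IGF2 encodes an insulin-like growth factor and neighbours H19 in the same imprinted region. The cluster named INS-IGF2, on the minus strand from 2150342 to 2182571 of chromosome 11, rose from 8.69 ± 0.22 to 10.08 ± 0.08 (SD, n = 3 each), 2.62-fold, at an adjusted p of 0.000265. A second cluster, named IGF2 and placed on the plus strand from 2153431 to 2153823, rose 2.24-fold at an adjusted p of 0.0015. It lies inside the span of the first, and the table gives it the opposite strand, so which transcript its probes read is not settled. PHLDA2, an imprinted gene that restrains placental growth, was 1.76-fold lower at an adjusted p of 0.000717. TNNI2, a troponin gene, rose 1.37-fold at an adjusted p of 0.0237. Of the 41 genes tested within 1 Mb of H19, 5 rose and 1 fell, a smaller share than the 17.6% called over all genes tested. The 5 include both overlapping clusters, and a cluster from 2356542 to 2356979 annotated as RPL26L1, away from that gene's own locus and named after its values were seen. The rest are TNNI2 and LOC402778, now IFITM10, which rose 1.64-fold (adjusted p = 0.0043 by limma). LOC402778 was also named after its values were seen. Among the 17 tested members of the fixed H19 neighbourhood list, 3 rose and 1 fell, also when adjusted over the list alone, and the list as a whole did not pass (camera adjusted p = 0.42). Leaving out control replicate 1 gave 6 rises.

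**Figure D1:**
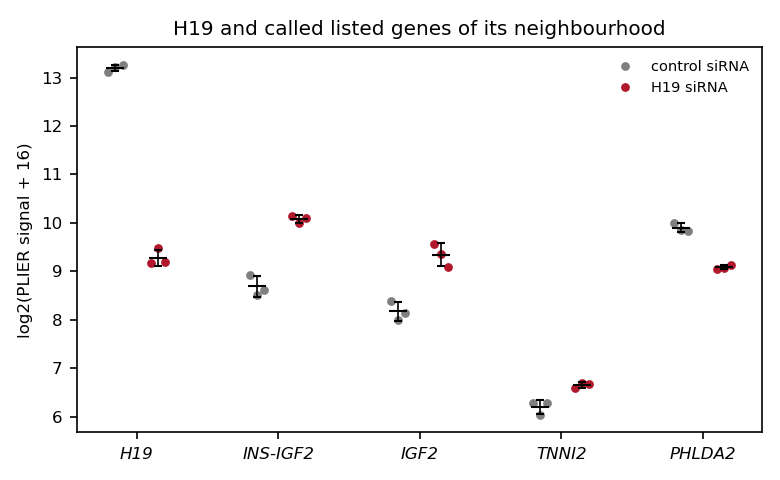
Levels of H19 and of the 4 genes of the neighbourhood list that changed, as log2(PLIER signal + 16). Points are arrays, horizontal marks are means and bars are SD (n = 3 per group). H19 was at 13.20 with control siRNA and 9.28 with H19 siRNA, while INS-IGF2 was at 8.69 and 10.08.

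Over all genes, H19 siRNA changed 3398 of 19322 genes tested (17.6%) at an adjusted p under 0.05, of which 1546 rose and 1852 fell. The change was at least 2-fold for 674 of them, 218 higher and 456 lower. In each of the 3398 genes the 3 control and the 3 H19 siRNA values did not overlap. The groups did not overlap in 7738 of the 19322 genes tested, where chance gives 10% for 3 against 3. Raised genes made up 45.5% of the calls, 35.1% when each array was centred on its median, and 55.9% without control replicate 1. The count changed strongly when control replicate 1 or an H19 siRNA array was left out. It was 8976 without control replicate 1, and 1597, 1669 and 1708 without H19 siRNA replicates 1, 2 and 3. Of the latter, 1592, 1663 and 1704 were among the 3398 genes, each in the same direction. Without control replicate 1, 3396 of the 3398 genes were called again, each in the same direction. That setting called 8976 of 19304 genes, 55.9% of them raised. A list's count with an array left out is therefore to be read against the count over all genes in the same setting.

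The largest rises among the called genes were in CYP4B1 and TXNIP. CYP4B1, a cytochrome P450 enzyme, went from 5.37 ± 0.42 to 8.80 ± 0.08 (SD, n = 3 each), 10.7-fold higher. TXNIP, which binds and inhibits thioredoxin, went from 8.56 ± 0.17 to 11.92 ± 0.05, 10.3-fold higher. CYP1B1, another cytochrome P450, rose 7.06-fold and CCL20, a chemokine, rose 6.93-fold. RASGRP1, an activator of RAS, rose 6.51-fold, and IFIT2, an interferon-induced gene, rose 6.17-fold. ARRDC3, an arrestin-related gene, rose 5.35-fold, and the complement protease C1S rose 5.33-fold. RARRES1, TNFAIP6, CEACAM7 and the serum amyloid gene SAA2 rose by 5.32-, 5.21-, 4.85- and 4.83-fold. The control mean of TNFAIP6 (4.70) lay below the median of the negative controls (4.91), so its fold depends on the offset of 16. Those of CYP4B1, RASGRP1 and IFIT2 (5.37, 5.35 and 5.21) lay near it, so their folds do as well. Control replicate 1 was the lowest control in all 12 genes except TXNIP and CEACAM7, which makes those folds larger than without it. In C1S it read 5.55, against 6.68 and 6.65 in the other controls. The adjusted p-values of these 12 genes lay between 8.46e-06 and 0.000824. SAA2 and SAA1 are near-identical in sequence, so signal shared between them is not excluded.

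After H19 itself, large falls were in IL1RL1, a receptor of the interleukin 1 receptor family, and TFPI2, a protease inhibitor, which were 9.15-fold and 8.68-fold lower. The proliferation marker MKI67 went from 7.90 ± 0.25 to 4.88 ± 0.34 (SD, n = 3 each), 8.10-fold lower, the inducible cyclooxygenase PTGS2 7.94-fold and the mitotic kinase PLK1 7.70-fold. KRT75, a keratin, was 7.53-fold lower, and IL1R2, a decoy receptor for interleukin 1, was 7.28-fold lower. The beta-defensin DEFB103A was 7.12-fold lower, RRM2, a subunit of ribonucleotide reductase, 6.96-fold, and the cytokine IL24 6.65-fold. Adjusted p-values of these falls, H19 left out, lay between 8.46e-06 and 0.000826. The H19 siRNA means of IL1RL1 (4.55) and MKI67 (4.88) lay below the median of the negative controls (4.91), so their folds depend on the offset of 16 and understate the change. Those of IL24 and PLK1 (5.22 and 5.43) lay near that median, so their folds depend on the offset as well. RRM2 read 5.35, 4.11 and 5.43 on the H19 siRNA arrays, so its fold also depends on the offset and rests in part on replicate 2. DEFB103A is read by clusters at a pair of duplicated loci with identical values, so the copies are not told apart.

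**Figure D2:**
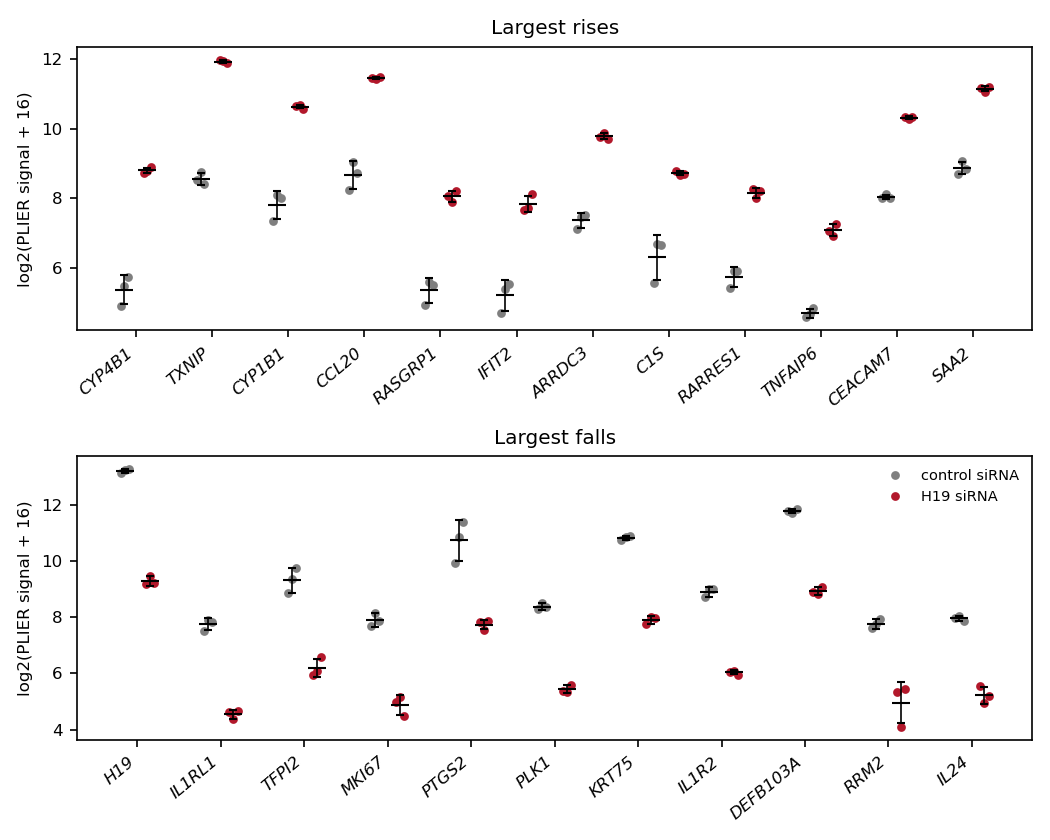
Levels of the 12 genes with the largest rises and of 11 of the 12 with the largest falls, as log2(PLIER signal + 16). Points are arrays, horizontal marks are means and bars are SD (n = 3 per group). In every gene shown the groups do not overlap, from CYP4B1 at 5.37 and 8.80 to IL24 at 7.96 and 5.22.

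Genes of the G2/M and mitosis list fell together. Of 63 tested members of the G2/M and mitosis list, 50 fell and none rose, with a median log2 change of -1.13, and 54 fell when adjusted over the list alone. The wider annotation terms mitosis and cell division, tested after the data were examined, had medians near 0 (-0.01 for each). In them 52 of 201 and 61 of 252 genes fell and 10 and 10 rose (camera adjusted p = 0.0149 and 0.0151, adjusted p = 0.995 for each with an estimated correlation). PLK1 was 7.70-fold lower, FOXM1, a transcription factor that drives mitotic genes, 6.12-fold, CDC20, an activator of the anaphase-promoting complex, 5.85-fold, and KIF20A, a mitotic kinesin, 4.07-fold. KIF20A fell to 4.86 ± 0.10 (SD, n = 3). Of 30 replication-dependent histone genes, which are expressed with DNA synthesis, 18 fell and none rose (22 fell adjusted over the list alone), with a median of -0.61. HIST1H3B was 6.15-fold lower and HIST1H3G 4.99-fold, though histone genes are similar enough for probes to be shared. The list of G1/S and DNA replication genes moved less evenly. Of its 43 members 10 fell and 2 rose (14 and 3 adjusted over the list alone), with a median of -0.07, or -0.18 without control replicate 1. RRM2, DTL, CDC6 and CDC45 were 6.96-, 3.43-, 2.84- and 2.28-fold lower, with DTL down to 4.79 ± 0.10 (SD, n = 3). The folds of KIF20A and DTL depend on the offset, as both ended below the median of the negative controls (4.91). That of RRM2 does too, as it read 4.11 in H19 siRNA replicate 2. HIST1H3G, CDC20, CDC45 and PLK1 ended near that median (5.07, 5.37, 5.43 and 5.43), so their folds do as well. The 2 that rose, named after their values were seen, were UNG, a repair glycosylase, and E2F8, a repressor among the E2F factors, at 1.49- and 1.38-fold higher. Camera gave adjusted p-values of 6.70e-34, 1.61e-12 and 0.00141 for the G2/M, histone and G1/S lists, and fry did not call the G1/S list (adjusted p = 0.103). The camera calls were lost with an estimated correlation (adjusted p = 0.297, 0.299 and 0.748 with an estimated correlation). Control replicate 1 differed from the other controls by a median log2 value of -0.42 in the G2/M list, -0.27 in the G1/S list and 0.32 in the histone list. Without it 58, 20 and 22 members of these lists fell, and 0, 5 and 2 rose. No G1/S gene rose without H19 siRNA replicate 2 or 3, and 1 rose without H19 siRNA replicate 1 or control replicate 3. The G1/S list did not pass with the lowest 25% of clusters left out (adjusted p = 0.0529).

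Genes of the sterol, fatty acid, and combined glycolysis and hypoxia lists fell as well. Of 26 sterol biosynthesis genes 21 fell and none rose (23 fell and 1 rose adjusted over the list alone), with a median log2 change of -0.69. EBP, a sterol isomerase, was 4.11-fold lower, MVD, of the mevalonate pathway, 2.96-fold and the cyclase LSS 1.98-fold. Of 25 fatty acid synthesis genes 12 fell and 1 rose (13 and 2 adjusted over the list alone), with a median of -0.42. The desaturases FADS2, FADS1 and SCD were 2.84-, 2.10- and 1.65-fold lower, and the acyltransferase AGPAT2 was 2.16-fold lower. A second cluster of SCD did not pass (log2 change -0.47, adjusted p = 0.322). Of 37 glycolysis and hypoxia genes 18 fell and none rose (24 and 1 adjusted over the list alone), with a median of -0.40. The glucose transporters SLC2A1 and SLC2A3 were 3.09- and 3.25-fold lower, ANGPTL4, an inhibitor of lipoprotein lipase, 4.37-fold, and PFKFB3, a regulator of glycolysis, 3.62-fold. The annotation term glycolysis, tested after the data were examined, did not pass, with 9 of 41 genes lower (adjusted p = 0.114). Camera gave adjusted p-values of 1.82e-15, 5.43e-06 and 8.69e-14 for the 3 lists, all lost with an estimated correlation (adjusted p = 0.297 with an estimated correlation for each). Control replicate 1 differed from the other controls by -0.34, -0.27 and -0.21 in the medians of these lists, and without it 25, 16 and 30 members fell and 1, 3 and 1 rose. Of the fatty acid genes 7, 7 and 9 fell and none rose without H19 siRNA replicates 1, 2 and 3, while 0 and 2 rose without control replicates 2 and 3. The list did not pass with a filter at the 95th percentile of the negative controls (adjusted p = 0.311).

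Genes of the matrix and of basal progenitor cells fell, and TGF-beta targets moved mostly down. Of 40 genes of the mesenchymal and matrix list 19 fell and none rose (21 and 3 adjusted over the list alone), with a median log2 change of -0.36. The galectin LGALS1 was 5.08-fold lower, the lysyl oxidase LOXL2 5.05-fold, the intermediate filament VIM 3.73-fold, and the fibronectin gene FN1 2.50-fold, from 12.80 ± 0.03 to 11.48 ± 0.05 (SD, n = 3 each). Of 30 TGF-beta targets 14 fell and 6 rose (16 and 6 adjusted over the list alone), with a median of -0.41. The matrix protein gene THBS1 and the transglutaminase TGM2 were 4.64- and 3.36-fold lower, while TNFAIP6, a hyaluronan-binding protein gene, rose from a level below the negative controls' median (4.70 ± 0.13, SD, n = 3). Of 29 limbal and basal progenitor genes 13 fell and none rose (14 and 2 adjusted over the list alone), with a median of -0.26. Those with the smallest p were ITGA6, an integrin that binds laminin, at 2.52-fold lower, the laminin chains LAMB3 and LAMA3 at 2.25- and 2.08-fold, and the WNT ligand WNT7A at 2.21-fold. Camera gave adjusted p-values of 7.95e-10, 8.47e-05 and 1.18e-05 for the 3 lists. None held with an estimated correlation (adjusted p = 0.16, 0.345 and 0.297 with an estimated correlation). Leaving out control replicate 1 gave 21, 19 and 15 falls and 4, 8 and 4 rises. Of 15 markers of keratocytes and fibroblasts 5 fell and none rose, but the median of that list was 0.01. Its falls in VIM, THY1, SPARC and COL5A2 are of genes on the matrix list as well, so they are not separate evidence.

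**Figure D3:**
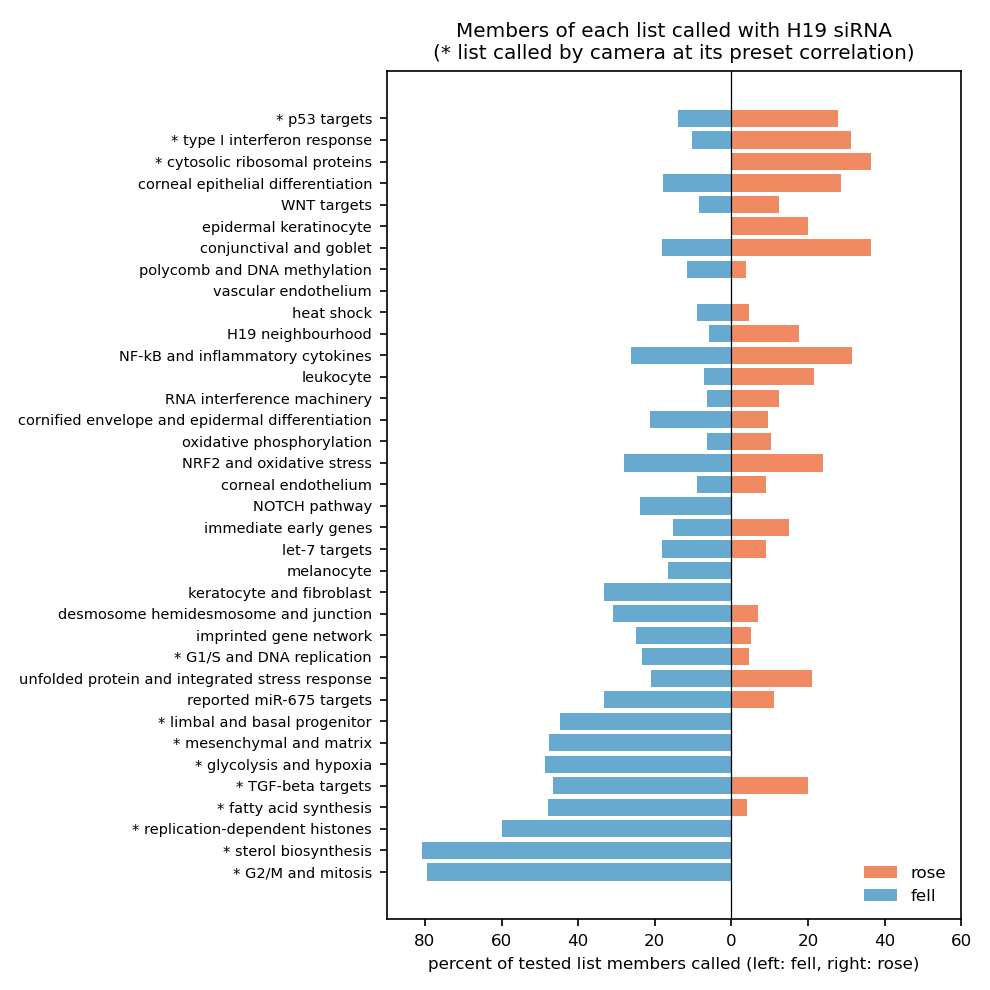
Share of the tested members of each of the 36 fixed lists that fell (left) or rose (right) at an adjusted p under 0.05, in percent of members, ordered by the list's median log2 change, with asterisks on lists called by camera at its preset correlation. The G2/M list (50 of 63 members fell) and sterol biosynthesis (21 of 26) reach farthest left, and cytosolic ribosomal proteins (16 of 44 rose) have no member on the left.

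The lists that shifted up were ribosomal proteins, interferon response genes and p53 targets. All 44 cytosolic ribosomal protein genes had a positive log2 change, 16 rose and none fell (25 rose adjusted over the list alone), with a median of 0.25. With each array centred on its median the list median was 0.19, and 10 members rose. RPS23 rose 1.45-fold, RPL34 1.39-fold, RPS6 1.34-fold and RPL7 1.33-fold, and the clusters read for RPL34 and RPL7 lie on chromosomes 19 and 5, away from the genes' own loci. Without control replicate 1 the list had 37 rises, and without H19 siRNA replicates 1, 2 and 3 it had 4, 3 and 4. Of 48 type I interferon response genes 15 rose and 5 fell (22 and 5 adjusted over the list alone), with a median of 0.26. IFIT2 rose 6.17-fold, IFI44 2.55-fold and RSAD2 2.13-fold, all interferon-induced, from levels near or below the median of the negative controls, so that these folds depend on the offset (5.21 ± 0.45, 4.41 ± 0.31 and 5.02 ± 0.15, SD, n = 3). PARP12, an interferon-induced ADP-ribosyltransferase, was 2.04-fold lower, and the antiviral membrane genes IFITM1, IFITM2 and IFITM3, named after their values were seen, fell by 0.48, 0.78 and 0.66 on the log2 scale. Of 36 p53 targets 10 rose and 5 fell (13 and 7 adjusted over the list alone), with a median of 0.29. GDF15, a stress cytokine, rose 2.62-fold and MDM2, which degrades p53, 2.57-fold, while PHLDA3, an inhibitor of AKT signalling, was 2.94-fold lower. Camera gave adjusted p-values of 9.93e-07, 0.0054 and 0.0408 for the 3 lists, none of which held with an estimated correlation (adjusted p = 0.297, 0.539 and 0.775 with an estimated correlation). Fry did not call the p53 list (adjusted p = 0.179). Control replicate 1 differed from the other controls by -0.27 in the median of the interferon list and by -0.27 in that of the p53 list. Without it 24 interferon genes rose and 7 fell, 17 p53 targets rose and 8 fell, and the p53 list did not pass (adjusted p = 0.182). Each H19 siRNA replicate left out gave 2 falls in the interferon list and 3 in the p53 list. Control replicate 2 left out gave 3 falls in each, and control replicate 3 left out 3 in the interferon list. The p53 call was also lost with an offset of 1 (adjusted p = 0.0526), with array weights (0.152) and without H19 siRNA replicate 2 (0.0651), and the interferon call with the lowest 25% of clusters left out (0.171).

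Genes of corneal and epidermal differentiation moved both ways. Of 28 corneal epithelial differentiation genes 8 rose and 5 fell, as they did when adjusted over the list alone (camera adjusted p = 0.263). CRNN, a marker of squamous epithelium, rose 3.17-fold, the epithelial transcription factors ELF3 and KLF5 1.81- and 1.46-fold, and the keratin KRT4 1.77-fold. CRNN read 8.34 in control replicate 1, against 9.26 and 9.20 in the other controls, which makes its fold larger than without that array. The corneal keratins KRT3 and KRT12 and the eye regulator PAX6, named after their values were seen, did not pass, with log2 changes of -0.02, -0.09 and -0.06. Of 52 cornified envelope and epidermal differentiation genes 5 rose and 11 fell (6 and 11 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.394). The late envelope genes LCE1C and LCE3E were 5.41- and 4.09-fold lower, CDSN, of the corneodesmosome, 2.34-fold, and the kallikrein KLK5 1.96-fold. In the epidermal keratinocyte list of 10 genes, KRT10 and KRT1, keratins of differentiating skin, rose 2.84- and 2.03-fold and none fell, also adjusted over the list alone (camera adjusted p = 0.3). The controls, in order of replicate, read 10.64, 11.41 and 11.90 for KRT10 and 10.62, 11.42 and 11.63 for KRT1. Control replicate 1 was the lowest, which makes both folds larger than without it. The junction list had 9 falls and 2 rises among 29 genes (9 and 4 adjusted over the list alone, camera adjusted p = 0.0638), and fry called it down (adjusted p = 0.0349). In it ITGA6, PKP2, CD151 and DSG2 were 2.52-, 2.45-, 2.00- and 1.97-fold lower. The junction list passed without control replicate 1 (adjusted p = 0.0197), without H19 siRNA replicate 3 (0.0446) and with array weights (0.0233). Without control replicate 1, 13 corneal genes rose and 7 fell, and 13 cornified envelope genes rose and 16 fell. The junction list then had 6 rises and 12 falls, and the epidermal keratinocyte list 4 rises and 1 fall. With any H19 siRNA replicate, or control replicate 3, left out 3 corneal genes fell. With any H19 siRNA replicate left out 3 or 4 cornified envelope genes rose, 0 or 1 junction genes rose and 1 epidermal keratinocyte gene rose.

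Inflammatory genes also split. Of 38 NF-kB and inflammatory cytokine genes 12 rose and 10 fell (13 and 11 adjusted over the list alone, camera adjusted p = 0.72). CCL20, SAA2 and SAA1 rose 6.93-, 4.83- and 4.22-fold, while IL1RL1, PTGS2 and IL24 were 9.15-, 7.94- and 6.65-fold lower. In the NRF2 and oxidative stress list 6 of 25 genes rose and 7 fell (6 and 10 adjusted over the list alone, camera adjusted p = 0.72). The aldo-keto reductase AKR1B10 rose 4.64-fold, the glutathione reductase GSR 2.07-fold and GCLC, of glutathione synthesis, 1.79-fold, whereas the heme oxygenase HMOX1 was 1.55-fold lower. In the list of unfolded protein and integrated stress genes 8 of 38 rose and 8 fell (8 and 9 adjusted over the list alone, camera adjusted p = 0.42). NUPR1, a stress-induced gene, rose 1.98-fold and PSAT1, of serine synthesis, 1.77-fold, while PPP1R15A and CALR were 1.74- and 1.63-fold lower. Of 33 immediate early genes 5 rose and 5 fell, also adjusted over the list alone (camera adjusted p = 0.263), and fry called the list down (adjusted p = 0.00249). IER3 was 3.29-fold lower, from 12.43 ± 0.07 to 10.72 ± 0.05 (SD, n = 3 each), and DUSP4, PHLDA1 and FOSL1 were 1.84-, 1.81- and 1.77-fold lower. Of 22 heat shock genes HSPD1 rose 1.73-fold and HSPB8 and DNAJB1 were 2.13- and 1.98-fold lower, 1 rise and 2 falls also adjusted over the list alone (camera adjusted p = 0.894). Control replicate 1 differed from the other controls by a median of -0.57 in the heat shock list and -0.28 in the unfolded protein list. It was the lowest control for AKR1B10, GSR, GCLC, NUPR1, PSAT1 and HSPD1, which makes those rises larger than without it. It was also the lowest for CALR, PPP1R15A, HSPB8 and DNAJB1, which makes those falls smaller. Without it 10 unfolded protein genes rose and 18 fell, 9 immediate early genes rose and 14 fell, 4 heat shock genes rose and 7 fell, and 8 NRF2 genes rose and 11 fell. The NF-kB list then had 16 rises and 13 falls. Leaving out H19 siRNA replicates 1, 2 and 3 gave 6, 7 and 6 falls in the NF-kB list and 3, 3 and 3 in the NRF2 list. It gave 3, 3 and 4 rises with 2, 3 and 2 falls in the unfolded protein list, 1, 1 and 2 rises in the immediate early list, and 0, 0 and 1 in the heat shock list. Control replicates 2 and 3, each left out in turn, gave 4 and 5 falls in the unfolded protein list and in the NRF2 list, 2 and 3 rises in the immediate early list, and 2 and 1 rises in the heat shock list.

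Lists tied to H19 in earlier work were not called by camera, which compares them with other genes. Fry, which does not, called the miR-675, let-7 and imprinted lists down (adjusted p = 0.000866, 0.00194 and 0.018). Their median log2 changes were -0.19, 0.03 and -0.07, and in the let-7 list 18 changes were positive and 15 negative. Of 18 reported targets of miR-675, a microRNA made from H19, 6 fell and 2 rose, also adjusted over the list alone (camera adjusted p = 0.0622). CDC6, TGFBI and CDH13 were 2.84-, 2.04- and 1.86-fold lower, and SMAD1 rose 1.57-fold. Of 33 let-7 targets 6 fell and 3 rose (9 and 7 adjusted over the list alone, camera adjusted p = 0.42). THBS1, CCND2 and CDC34 were 4.64-, 1.53- and 1.51-fold lower and MYC rose 1.35-fold. CDC6 is also on the G1/S list, and TGFBI and THBS1 are on the TGF-beta list, so their falls are not separate evidence. Of 20 genes of the imprinted gene network 5 fell and 1 rose, also adjusted over the list alone (camera adjusted p = 0.0671). They include PHLDA2, and the rise is that of the plus-strand cluster named IGF2, whose transcript is not settled. MEG3 and SLC38A4 were 1.58- and 1.55-fold lower. The miR-675 list passed without control replicate 3 (adjusted p = 0.0329) and without H19 siRNA replicate 3 (0.0362). When control replicate 1 was left out, 4 miR-675 targets rose and 7 fell, 11 let-7 targets rose and 11 fell, and 2 imprinted genes rose and 7 fell. Leaving out H19 siRNA replicates 1, 2 and 3 gave 4, 3 and 4 falls in the miR-675 list, 2, 3 and 3 in the let-7 list and 3, 1 and 1 in the imprinted list, which had 3 without control replicate 3. It gave 1, 0 and 1 rises in the miR-675 list and 0, 0 and 1 in the let-7 list, which had 1 rise and 3 falls without control replicate 3.

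The remaining fixed lists, those of cell type markers aside, were called by neither camera nor fry for a common direction. In the NOTCH list 5 of 21 genes fell and none rose (3 fell without H19 siRNA replicate 2), with JAG2, HES5 and NRARP 1.83-, 1.85- and 1.80-fold lower, as it did adjusted over the list alone (camera adjusted p = 0.3). Of 24 WNT targets 3 rose and 2 fell (4 and 2 adjusted over the list alone, camera adjusted p = 0.717), and the WNT inhibitor DKK1 was 4.45-fold lower. Oxidative phosphorylation had 5 rises and 3 falls among 48 genes (3 and 2 adjusted over the list alone, camera adjusted p = 0.841). SDHD rose 1.62-fold, read by a cluster on chromosome 1, away from the gene's own locus. Of 16 RNA interference genes XPO5 and ADAR rose 1.28- and 1.32-fold and TNRC6A was 1.31-fold lower (2 rises and 3 falls adjusted over the list alone, camera adjusted p = 0.72). Of 26 polycomb and DNA methylation genes 1 rose and 3 fell, also adjusted over the list alone (camera adjusted p = 0.762), with MBD1 2.02-fold lower. Without control replicate 1, 16 oxidative phosphorylation genes rose and 9 fell, 10 WNT targets rose and 4 fell, and 6 RNA interference genes rose and 4 fell. In the same setting 8 polycomb genes rose and 3 fell, and 5 NOTCH genes rose and 7 fell. Leaving out H19 siRNA replicates 1, 2 and 3 gave 0, 0 and 1 rises with 0, 1 and 0 falls in oxidative phosphorylation, 0, 0 and 1 rises in the WNT list, and 0 rises with 1 fall each in the polycomb list. None of the RNA interference genes was then called by limma. With control replicate 2 or 3 left out 1 polycomb gene fell and none rose, and 2 or 1 RNA interference genes rose and none fell. Control replicate 3 left out gave 1 rise in the WNT list and 1 fall in oxidative phosphorylation. The median was above 0 but the mean and the test pointed down in the let-7, cornified envelope, NOTCH, immediate early, keratocyte and melanocyte lists. In the NRF2, heat shock and corneal endothelium lists only the test pointed down, and in the WNT list only the mean was negative (-0.003).

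Camera called no list of markers of other cell types at n = 3 per group, while fry called the keratocyte list down (adjusted p = 0.000866) and the conjunctival list up (adjusted p = 0.0349). Of 15 keratocyte and fibroblast genes 5 fell and none rose, among them VIM, THY1 and SPARC at 3.73-, 2.30- and 1.71-fold lower (5 falls and 1 rise adjusted over the list alone, camera adjusted p = 0.0671). Of 12 melanocyte genes MITF and KIT fell by 1.09 and 0.59 on the log2 scale and none rose, also adjusted over the list alone (camera adjusted p = 0.669). Of 11 conjunctival and goblet genes 4 rose and 2 fell, with CLCA4 4.24-fold higher and KRT8 and KRT7 1.44- and 1.34-fold lower (4 and 3 adjusted over the list alone, camera adjusted p = 0.598). The control mean of CLCA4 (5.02) lay near the median of the negative controls (4.91), so its fold depends on the offset. Of 14 leukocyte genes 3 rose and 1 fell, with CD14 2.08-fold higher and CD68 1.33-fold lower, also adjusted over the list alone (camera adjusted p = 0.521). Of 11 corneal endothelium genes CA12 rose 1.52-fold and SLC4A11 was 1.49-fold lower, also adjusted over the list alone (camera adjusted p = 0.841). None of 9 vascular endothelium genes passed by limma, over all genes or adjusted over the list alone (camera adjusted p = 0.454), with TIE1 at a log2 change of 0.39 (adjusted p = 0.0514). When control replicate 1 was left out, 4 of them were called higher, in a setting that called 8976 of 19304 genes. The same setting gave 2 rises each in the melanocyte and keratocyte lists, with 2 and 5 falls, 5 rises and 1 fall in the leukocyte list, 5 rises and 3 falls in the conjunctival list, and 3 rises and 3 falls in the corneal endothelium list. With any H19 siRNA replicate left out 2 conjunctival genes rose, 1 or 2 leukocyte genes rose, 3 or 4 keratocyte genes fell, 1 melanocyte gene fell and no leukocyte gene fell. No corneal endothelium gene rose without H19 siRNA replicate 2, and 1 conjunctival gene fell without H19 siRNA replicate 1 or 3. Control replicate 2 left out gave 2 rises and 1 fall in the conjunctival list and no fall in the leukocyte list, and control replicate 3 left out 1 fall in the melanocyte list. The keratocyte list passed without control replicate 2 (adjusted p = 0.0479), control replicate 3 (0.0485) or H19 siRNA replicate 3 (0.0201), and with the lowest 25% of clusters left out (0.00335).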

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

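Of the tests in this part, that of the small RNA genes was chosen before its result was seen, and the others after. Clusters with no gene symbol, which the comparisons above did not use, were seldom called. Of 4534 such clusters above the median of the negative controls, 9 rose and 10 fell by limma, and 500 had an unadjusted p under 0.05. Of the 19322 genes tested, 3398 were called by limma (17.6%), and 6014 had an unadjusted p under 0.05. The 2904 negative controls and the 1195 positive controls had 0 calls in either direction by limma, with unadjusted p under 0.05 for 222 and 259 of them and median log2 changes of 0.03 and 0.16.

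With 3398 genes called for the real groups, the highest count among the other splits of the 6 arrays was 0. The real split was the 1 split of 10 with as many genes. With 10 splits the share cannot go under 0.1, which is too few splits for a share under 0.05.

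Control replicate 1 stood apart from the other controls, with a mean correlation of 0.967 against 0.995 between controls 2 and 3. Genes for small nuclear and nucleolar RNAs were higher in it, by a median of 0.75 on the log2 scale over 215 genes. Without them its correlation was 0.968, so the difference was not confined to them. Leaving out 215 of 19322 genes can move a correlation only slightly, so this does not decide what their signal means in control replicate 1. Its median absolute log2 difference from the other controls was 2.81 times that between controls 2 and 3, and 2.71 times after quantile normalization, which argues against a difference in scale between arrays as the whole cause. Its H19 level of 13.12 argues against a swap with an H19 siRNA sample. The state of the cells or the quality of that RNA may still account for it, and no value here tests either.

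Genes of the G2/M list were lower with H19 siRNA. After the trend of log2 change on mean level was subtracted, the median of the G2/M list was -1.21, so a shift that depends on signal level does not account for it. The difference between the medians of the G2/M and G1/S lists changed by -1.25 between the groups, against a spread of 0.15 between arrays, which argues against an equal fall of all cell cycle genes. An effect of lower H19, a lower share of cells in mitosis, and effects of either siRNA pool on other genes stay open and were not tested.

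Interferon response genes rose in part. Without control replicate 1 the median log2 change of the list was 0.27, against 0.26 with it, so leaving it out did not lower that median. The list medians of the arrays, with a spread of 0.13, lay closer together. They were 6.88, 7.12 and 7.12 with control siRNA and 7.10, 7.22 and 7.34 with H19 siRNA. H19 siRNA replicate 1 thus lay below control replicates 2 and 3, so low values in control replicate 1 as part of the source stay open. The camera adjusted p was 0.0421 without that array and 0.0054 with it. The 15 members called higher with all arrays could come from the siRNA duplexes themselves or from lower H19. These cannot be told apart, because each group received a pool of its own from a different supplier.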

How the results depend on the processing

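Under 18 alternatives the H19 level stayed lower and past the threshold, with log2 changes from -4.01 to -3.86 and adjusted p-values from 7.34e-18 to 0.000159. The filter that leaves out the lowest 25% of clusters was added after seeing the data and gave 3310 genes and 11 lists. Over the alternatives 150 other named genes gave 2571 values, of which 2443 kept direction and side of the threshold, 98 no longer passed, 30 newly passed and none reversed. The genes changed by H19 siRNA, genes raised by H19 siRNA and genes lowered by H19 siRNA were 393, 159 and 234 with the 95th-percentile filter, which tests 942 genes. They were 8853, 4990 and 3863 with array weights, which gave control replicate 1 a weight of 0.083. A 1.5-fold threshold gave 1962, 819 and 1143, an unadjusted p under 0.05 gave 6014 changed and 3309 raised, and an adjusted p under 0.10 gave 2467 raised. Leaving out an array gave 1597 to 8976 changed, 542 to 5021 raised and 1034 to 3955 lowered, the highest without control replicate 1, and lowest counts each without an H19 siRNA array. Lists called were 6 with the 95th-percentile filter, 0 with an estimated correlation by camera (17 by fry) and 35 by fry for changes in either direction. Apart from the fewer genes or arrays tested and the thresholds themselves, the cause was not tested. The share of positive controls above negative ones was 0.881 to 0.902, so signal over background limits what dim genes can show. The second deposited table was not run, as its values are identical.

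Same-numbered arrays of the groups had correlated deviations of 0.151, 0.143 and 0.0589, not all over 0.1, so the numbers were not taken to pair samples. With a replicate block the genes changed by H19 siRNA were 2873 (genes raised by H19 siRNA 1258, genes lowered by H19 siRNA 1615), with 12 lists called, and 4 let-7 targets rose and 3 fell. In these deviations each of the 6 arrays correlated best, across groups, with the array of its own number, a hint from the data and not from the design.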

Other observations

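The tests in this part were chosen after the report's results were seen, and for the YAP/TAZ genes before those genes' own values were. Among 714 annotation terms of the deposited table, camera called 5 up and 26 down at its preset correlation, and 0 held with an estimated correlation (32 had an unadjusted p under 0.05). Translational elongation shifted up, with 31 of 92 genes higher and none lower (adjusted p = 5.67e-07), and so did tRNA processing (11 of 62 higher, 2 lower, adjusted p = 0.00506) and rRNA processing (14 of 91 higher, 4 lower, adjusted p = 0.0123). The term actin cytoskeleton organization shifted down, with 29 of 112 genes lower and 4 higher (adjusted p = 0.00141), and so did cell-matrix adhesion, with 18 of 71 lower and 3 higher (adjusted p = 0.0128). Protein polymerization (14 of 27 lower, none higher, adjusted p = 1.51e-06) and microtubule-based movement (26 of 87 lower, 3 higher, adjusted p = 0.003) also shifted down by camera. The adjusted p with an estimated correlation was 0.995 for each of these terms. The broader term cytoskeleton organization (adjusted p = 0.23) and microtubule cytoskeleton organization (adjusted p = 0.0992) did not pass. The keratinization term shifted down with 17 of 39 genes lower and 2 higher (adjusted p = 0.000122), although the fixed cornified envelope list did not pass.

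CYR61, CTGF, THBS1 and AXL fell together, which led to the hypothesis that transcription driven by YAP and TAZ, coactivators that respond to cell shape and adhesion, may be lower. Of 19 other reported targets, 10 fell and 1 rose, with a median log2 change of -0.38 (camera, adjusted p = 4.21e-06 over the 2 lists added here, adjusted p = 0.0421 with an estimated correlation). By camera with an estimated correlation the unadjusted p was 0.0211, against 0.00444 for the matrix list and 0.0275 for the G2/M list. Those were adjusted over 36 lists and did not hold, so the adjusted values cannot be compared. NT5E, DOCK5 and CRIM1 fell by 1.80, 1.20 and 1.09 on the log2 scale, and IGFBP3 rose by 0.42. The values go with the hypothesis, but the list was prompted by genes of the same data, and an effect of the siRNA pools is not excluded. Of the prompting genes, CYR61, CTGF and THBS1 are also on the fixed TGF-beta list, so their falls are not separate evidence.

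TXNIP and ARRDC3 rose while mitotic genes fell, which led to the hypothesis of a quiescence programme of the FOXO type. Of 21 other reported genes 4 rose and 2 fell, with a median log2 change of 0.15 (camera, adjusted p = 0.203 over the 2 added lists, adjusted p = 0.569 with an estimated correlation). SESN1, SESN3, PIK3IP1 and FBXO32 rose by 1.34, 0.91, 0.88 and 0.61, and CCNG2 and PINK1 fell by 0.94 and 0.66. The median lay between the bounds set for and against the hypothesis, so the test leaves it open.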
